A study of Mus musculus with 8 samples.

How the data were processed

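The series measured Hepa1-6 cells in 8 libraries: 2 each of untreated control, TMAO at 50 µM, TNF-α at 50 ng/ml and both, exposed for 24 h per the labels. Per the labels' protocols, mRNA was selected with oligo-dT beads from Trizol extracts, fragmented and made into cDNA libraries, and sequenced on an Illumina instrument as paired reads of 150 bases, from cells grown in DMEM with 10% fetal bovine serum. The group of each library was taken from its title. Per the submitters' processing notes the genome build was mm9; the aligner, the annotation release, trimming and the strand setting are not given in the sources used here.

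The authors deposited a table of counts, whole numbers per versioned Ensembl gene identifier and library, whose name names htseq as the counter, with no version or settings. The authors also deposited a table of TPM values per gene symbol, each column summing to about 1e6 by its own values; the program that made it is not given in the sources used here. Neither table pools replicates, and all 8 value columns of each were used. The count table has 54446 genes, of which 24472 had 0 counts in every library. Of its identifiers 53229 matched the GENCODE M21 annotation with their version and 54409 without it, and 37 had no symbol. Symbols and gene classes came from that annotation, as did gene length (from its exons) and GC content (from its transcripts). No coordinates are printed, since the build differs. Among the TPM values 191 symbols occur more than once and 27 had been turned into dates, and these were left out of the TPM comparison.

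Counts were compared with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept (15613), libraries were scaled by TMM, and a model with 4 group means was fitted to all 8 libraries with glmQLFit (robust), leaving 4 residual degrees of freedom. Contrasts were tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, with no fold limit. The contrasts were TMAO against control, TNF-α against control, both against control, both against TNF-α, both against TMAO, the interaction, and each agent averaged over the other. CPM values are counts scaled by the total of the kept genes times the TMM factor, without a pseudocount. Values for libraries on the log2 scale used a prior count of 2. The test, the groups, the gene lists, the rule for named genes and all settings but the last 3 named were chosen before the data were examined.

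Gene lists (38) were tested with camera in limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry, a rotation test of whether the genes of a list move one way, with adjustment over the 38 lists in each comparison. A list's direction in camera is relative to the other genes. Members were also adjusted over the list alone. No list called at the preset correlation was called with an estimated correlation in any of the first 6 contrasts. Where a list mean is given beside a left-out library, both means are of log2 CPM differences, which is another measure than the median of fitted fold changes.

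Named genes were chosen by rule: among called genes with at least 1 CPM on average in a group and both libraries of 1 group beyond both of the other, the 10 with the largest and the 10 with the smallest log2 fold change, leaving out unnamed predicted genes; the 4 members with the smallest p of each list that passed, and always of the list of flavin monooxygenases and choline metabolism; and, where fewer than 5 genes passed, the 5 with the smallest p. The rule had 607 genes to choose from with TNF-α against control and 524 with both against control, 59 of them unnamed in each. In some lists a gene that the rule chose is not reported here. In the plot of single genes for TMAO, Slc2a1 and Ddit4 were added after their values were seen.

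The depth of 24736746 to 30488605 counts per library puts the limit that 3 counts set at 0.0984 to 0.121 CPM, which covers counting error only. For the 8990 genes with at least 10 CPM the median half-width of the 95% interval of a log2 fold change was 0.41 for pairs of groups, 0.58 for the interaction and 0.29 for averaged contrasts. These intervals use the 4 residual degrees of freedom alone and no adjustment over genes, so they are not the limit of detection of the adjusted tests. The programs were tested on simulated counts with the real means and library sizes and 200 changed genes. For TNF-α against control, over 15613 genes, edgeR recovered 7.46% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 93.9% of those changed 4-fold, with 2 of 98 calls among unchanged genes. For TMAO against control 7 of 110 edgeR calls and 35 of 170 DESeq2 calls were among unchanged genes. For the interaction edgeR recovered 0% (1.5-fold), 14.9% (2-fold) and 81.8% (4-fold).

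The other settings tried were DESeq2 1.42.0, limma-voom, scaling by DESeq2's method (RLE) or by total counts, no filter on low counts, a filter of at least 1 CPM in 2 libraries, fits of only the groups compared, the library number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), a limit of 2-fold, and leaving out each library. After the data were seen, fits without TNF-α 16 and control 14, with library weights, and with an offset for gene length and GC content were added. Where a library left out leaves a group with 1, that library is assumed to vary like the other groups. Without TNF-α 16 and control 14, the TNF-α and control groups have 1 library each. All spread then comes from the TMAO and combined pairs, so counts from that fit are not those of a replicated comparison. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.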

Results

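Gene expression was measured by bulk mRNA sequencing in Hepa1-6 cells, a mouse hepatoma line given in the labels as of C57BL/6 origin. There were 4 groups of 2 libraries each: untreated control cells, cells given trimethylamine N-oxide (TMAO) at 50 µM, cells given the inflammatory cytokine TNF-α at 50 ng/ml, and cells given both. TMAO is an oxidised amine that arises from dietary choline through gut bacteria and the liver. Exposure lasted 24 h. The libraries of each group carry the numbers 14 and 16, whose meaning the labels do not give, and the labels do not say that they came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Total counts ran from 24736746 (TNF-α 16) to 30488605 (TMAO 16). Between 20815 and 22917 of the 54446 listed genes had at least 1 count in a library. A label of the combined group names TMAO for both agents, whereas its titles and the treatment protocol name TMAO and TNF-α. A list of NF-κB target genes, 26 of them measured, was fixed before the data were examined. Its mean log2 CPM was 6.18 and 6.21 in the combined libraries, 6.24 and 6.35 in the TNF-α libraries, and 5.11 to 5.2 in the 4 libraries without TNF-α. Genes are given by symbol, the leading ones also by identifier. No coordinates are given, because the processing notes name build mm9 and the identifiers match a later annotation.

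The libraries of a group differed unequally. The SD of the log2 difference between the paired libraries over expressed genes was 0.29 in the TMAO group, 0.31 in the combined group, 0.35 in the control group and 0.77 in the TNF-α group. In the TNF-α group 5135 of 14443 genes (35.6%) lay more than 1.5-fold apart, against 8.71% in the control group, 6.46% in the TMAO group and 5.93% in the combined group. TNF-α 16 stood apart from the other 7 libraries, with a median correlation of 0.967 across genes where the other libraries had 0.981 to 0.983. Control 14 departed the same way to a smaller extent. After group means were removed, the first principal component (64.6% of the variance) put TNF-α 16 at -51.0 and control 14 at -13.6. Ribosomal protein genes had a mean log2 CPM of 10.50 in TNF-α 16 and 9.65 to 9.92 in the other 7 libraries. Control 14 had the 9.92, against 9.72 to 9.74 in control 16 and the TMAO libraries. Nuclear genes of oxidative phosphorylation stood at 7.18 in TNF-α 16 and at 6.52 to 6.80 elsewhere. Control 14 had the 6.80, against 6.63 to 6.65 in control 16 and the TMAO libraries. Genes of antioxidant enzymes stood at 6.70 and at 6.05 to 6.20 elsewhere. In every group the counts differed by more than sampling noise, with a chi-square per gene of 2.02 (TMAO), 2.98 (combined), 14.8 (control) and 145 (TNF-α), so no library was a copy of another.

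**Figure D1:**
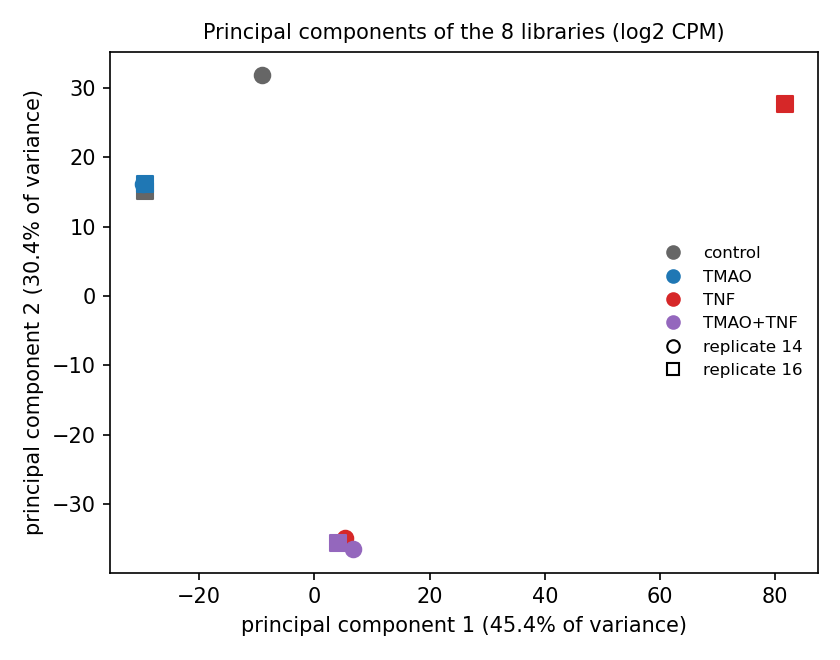
Position of each of the 8 libraries on the first (45.4% of the variance) and second (30.4%) principal component of log2 CPM, coloured by group, with circles for number 14 and squares for number 16. TNF-α 16 lies at 81.8 on the horizontal axis, and TNF-α 14 at 5.25 beside the combined libraries at 6.67 and 4.08. Of the 4 libraries without TNF-α, control 14 lies at -9.09 and the others between -29.8 and -29.4.

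TNF-α alone was compared with control to find the genes that changed with the cytokine. Pglyrp2 (ENSMUSG00000079563.9), a secreted amidase that cleaves bacterial peptidoglycan, rose from 1.88 ± 0.263 to 55.3 ± 3.75 CPM (mean ± SD, n = 2 per group), a log2 fold change of 4.88 ± 0.16 (± SE) or 29.4-fold. Cd83, a surface protein of activated immune cells, rose from 4.21 ± 0.0614 to 52.3 ± 14.2 CPM (3.63 ± 0.21 on the log2 scale). Tnip3, an inhibitor of NF-κB signalling that binds A20, rose from 1.27 ± 0.597 to 13.2 ± 0.467 CPM (3.38 ± 0.30). The chemokine Cxcl15 (ENSMUSG00000029375.6) fell from 32.5 ± 0.168 to 3.29 ± 0.257 CPM (-3.31 ± 0.13). Notum, a secreted carboxylesterase that inactivates Wnt proteins, fell from 18.3 ± 3.22 to 2.5 ± 0.678 CPM (-2.88 ± 0.22). Tenm4, a teneurin of the cell surface, fell from 4.87 ± 0.768 to 0.240 ± 0.0117 CPM. The gene of the secreted epidermal protein Dmkn fell from 2.61 ± 0.518 to 0.351 ± 0.263 CPM. From low control levels, Sorcs1, a sorting receptor, rose by 4.83 on the log2 scale to 5.43 ± 1.49 CPM. Acod1, the enzyme that makes itaconate, rose by 3.97 to 4.09 ± 1.29 CPM, and Spib, an ETS transcription factor, by 3.77 to 4.71 ± 0.713 CPM. Extl1 rose from 0.0676 to 3.52 CPM and growth hormone (Gh) from 0.0848 to 1.39 CPM, with so few control counts that no fold is given. The Wnt5a receptor gene Ror2 fell from 1.09 to 0.0703 CPM. H2-Q1 (45.5 to 4.81 CPM), H2-M2 (0.205 to 2.32), Sprr2e (1.12 to 40.4), Krtap1-5 (1.53 to 0.0827) and Krt33b (1.42 to 0.0910) also passed the test but belong to multigene families whose reads can be shared. Notumos (2.69 to 0.318) and Bcas3os2 (2.13 to 0.0786) passed as well, and are antisense genes whose reads cannot be told from their partners without the strand. These 7 genes are uncertain.

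Among the gene lists fixed before the data were examined, NF-κB targets were higher with TNF-α. Of 26 measured, 19 rose over all genes tested and 22 adjusted over the list alone, with none lower. The list had a median log2 fold change of 1.0 and a camera adjusted p of 5.14e-23 (adjusted p = 0.0891 with an estimated correlation). They included the adhesion molecule Vcam1 (56.7 ± 2.82 to 247 ± 14.9 CPM, 2.12 ± 0.10) and Tnfaip2 (3.22 ± 0.124 to 19.4 ± 0.572, 2.58 ± 0.12). Also higher were the signalling adaptor Traf1 (19.5 ± 0.0645 to 132 ± 34.8, 2.76 ± 0.18) and the monocyte chemoattractant Ccl2 (179 ± 21.9 to 1137 ± 208, 2.66 ± 0.17). Of 21 cytokines and chemokines, 13 rose and Cxcl15 fell, or 17 and 1 adjusted over the list alone. Their median was 1.04, with an adjusted p = 1.13e-12 (adjusted p = 0.246 with an estimated correlation). Cxcl16 rose by 1.78, Ccl9 by 2.25 and Ccl20, a ligand of CCR6, by 1.78 on the log2 scale. The cytokine list stood at a mean log2 CPM of 4.34 in TNF-α 14 and 4.71 in TNF-α 16, against 3.29 to 3.45 without TNF-α. Of 28 interferon-stimulated genes, 2 rose, and 7 rose and 1 fell adjusted over the list alone. Interferon-stimulated genes had a median of 0.35 (adjusted p = 0.000354; adjusted p = 0.129 with an estimated correlation). The genes that rose encode the guanylate-binding proteins Gbp3 (1.21 ± 0.10) and Gbp2 (1.28 ± 0.13), close paralogs and so uncertain. Mx2 had 0.44 and Dhx58 0.43, neither past the test. Of 14 genes of MHC class I presentation, 3 rose, or 8 adjusted over the list alone. These genes had a median of 0.60 (adjusted p = 9.44e-05; adjusted p = 0.466 with an estimated correlation). The 3 were the peptide transporter subunit Tap2 (10.8 ± 1.95 to 23.2 ± 4.46 CPM), tapasin (Tapbp, 136 ± 10.9 to 259 ± 72.4) and the immunoproteasome subunit Psmb9 (8.88 ± 1.88 to 18.2 ± 4.44). Tap1 had 0.43 and did not pass. The MHC class I list was at a mean log2 CPM of 6.60 in TNF-α 14 and 7.01 in TNF-α 16. Its mean log2 fold change of 0.57 was 0.38 without TNF-α 16.

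Of 15 measured genes of hepatocyte identity, 3 fell with TNF-α. Albumin (Alb, ENSMUSG00000029368.10) fell from 1197 ± 43.7 to 401 ± 58.2 CPM (-1.58 ± 0.14). Alpha-fetoprotein (Afp) fell from 1551 ± 57.4 to 723 ± 141 CPM (-1.10 ± 0.16) and Hnf4a, a nuclear receptor that controls hepatocyte genes, from 211 ± 2.85 to 128 ± 22.5 CPM (-0.72 ± 0.13). Adjusted over the list alone, 6 were lower and 1 higher, and Onecut1 had -1.35. Hepatocyte genes had a median of -0.43 (adjusted p = 0.000264; adjusted p = 0.129 with an estimated correlation). Of 24 genes of cholesterol synthesis and uptake, 2 fell, or 9 adjusted over the list alone. Cholesterol genes had a median of -0.32 (adjusted p = 6.16e-06; adjusted p = 0.0960 with an estimated correlation). Squalene epoxidase (Sqle) fell from 268 ± 4.71 to 169.6 ± 8.32 CPM (-0.66 ± 0.10) and the reductase Dhcr7 from 34.6 ± 0.890 to 24.4 ± 0.665 CPM. Nsdhl (-0.54) did not pass. Of 18 genes of fatty acid and triglyceride synthesis, the stearoyl-CoA desaturase Scd1 fell (264 ± 16.6 to 147 ± 33.0 CPM), with 2 lower adjusted over the list alone. Scd2 (-0.69), Fads2 (-0.33) and Elovl5 (-0.26) did not pass over all genes. Fatty acid synthesis genes had a median of -0.28 (adjusted p = 0.0127; adjusted p = 0.466 with an estimated correlation). That list's mean of -0.27 was -0.10 without TNF-α 16, with an adjusted p of 0.0806, and -0.43 without TNF-α 14. Ribosomal protein genes passed as a list (28 genes, median 0.31, adjusted p = 0.0210; adjusted p = 0.754 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone in edgeR. Rps19 had 0.45, Rpl5 0.34, Rpl13 0.40 and Rpl19 0.37. Their list mean of 0.26 turned to -0.15 without TNF-α 16 (adjusted p = 0.000674), was 0.67 without TNF-α 14, and was 0.17 without control 16 (adjusted p = 0.189). Of 13 genes of flavin monooxygenases (which oxidise trimethylamine) and choline metabolism, 0 passed over all genes in edgeR and 3 fell adjusted over the list alone (list median -0.20, adjusted p = 0.144). Fmo1 stood at 0.546 and 0.0868 CPM in control and TNF-α. Fmo2 had -0.72, Slc44a1 -0.42 and Pemt 0.41.

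In all, TNF-α changed 633 of 15613 genes (372 higher, 261 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 395 of them at least 2-fold. Named genes passed at an adjusted p of 0.000166 (Pglyrp2) to 0.0480 (Psmb9). The count rested on the spread shared by all groups and was 7966 without TNF-α 14, 2085 without TNF-α 16 and 92 and 99 without control 14 or 16. It was 276 and 273 without TMAO 14 or 16, 262 and 261 without combined 14 or 16, and 3 when only the control and TNF-α libraries were fitted (Pglyrp2 higher, Cxcl15 and H2-Q1 lower). Without both TNF-α 16 and control 14, a setting chosen after the data were seen, 3278 genes passed (1664 higher, 1614 lower), among them 623 of the 633. The 38 named genes that passed were also followed in the fits without each library. Leaving out either TNF-α library removed the widest difference within a group from the shared spread, so passing there is no check on these calls. This holds for the combined exposure below as well. Gh, Krtap1-5, Dmkn, Tap2, Tapbp, Psmb9, Sqle, Dhcr7, Scd1, Afp and Hnf4a did not pass when any of the control, TMAO or combined libraries was left out (adjusted p up to 0.313). H2-M2, Bcas3os2, Krt33b, Notumos and Ror2 did not pass when either control library was left out (up to 0.110), nor Ror2 without combined 16, Sorcs1 without control 14 (0.0516) and Gbp2 without control 16 (0.0570).

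**Figure D2:**
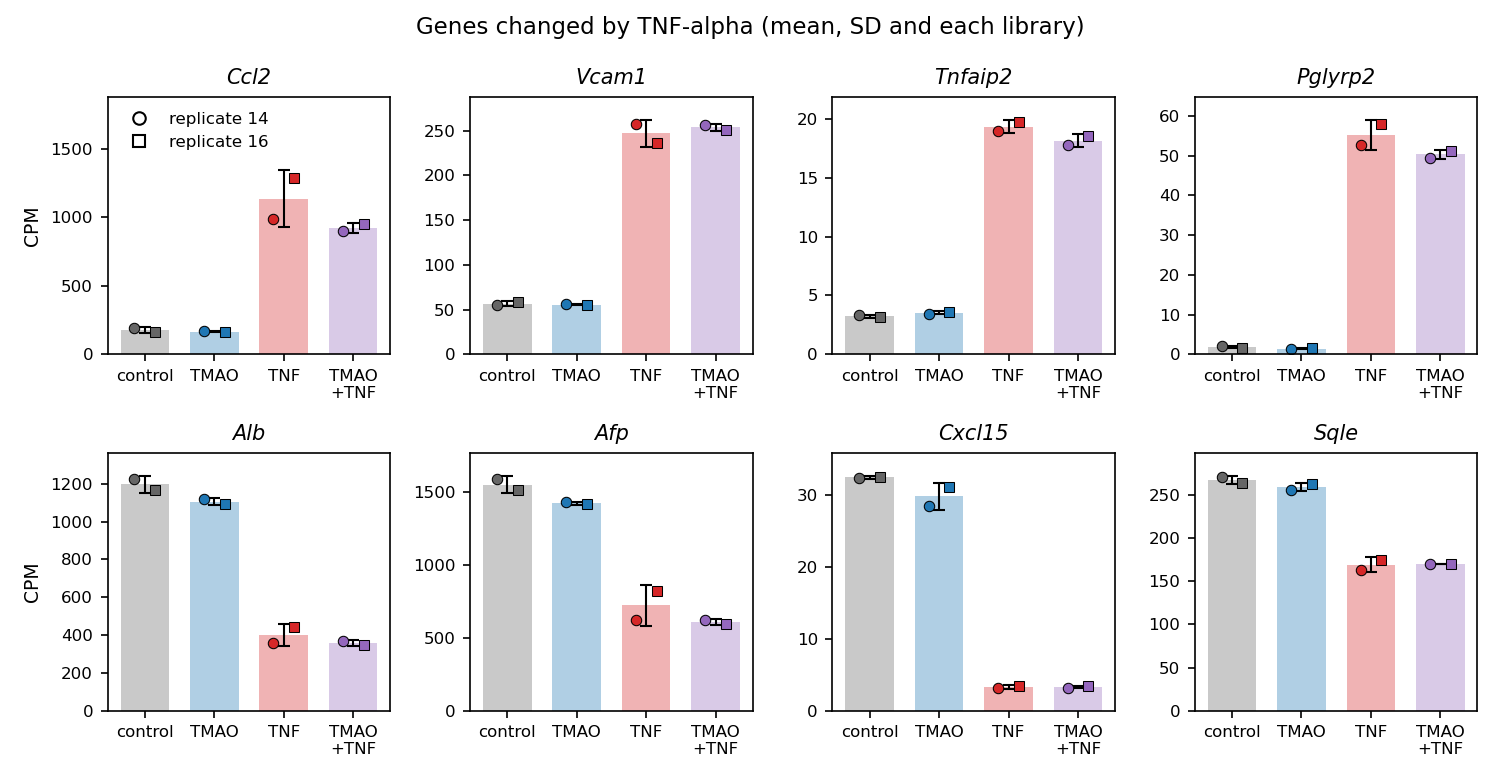
Expression of Ccl2, Vcam1, Tnfaip2, Pglyrp2, Alb, Afp, Cxcl15 and Sqle in the 4 groups, in CPM (vertical axis); bars are means of 2 libraries, error bars the SD, and points the single libraries. Ccl2 stood at 179 ± 21.9 CPM in control and 1137 ± 208 with TNF-α, and Alb at 1197 ± 43.7 and 401 ± 58.2.

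TMAO and TNF-α together were compared with control to find the genes that changed with the combined exposure. Pglyrp2 rose to 50.4 ± 1.20 CPM (4.74 ± 0.16), and Vcam1 to 254 ± 3.97 CPM (2.16 ± 0.10), each with n = 2. Gdnf, a neurotrophic factor, rose from 1.37 ± 0.405 to 15.8 ± 1.34 CPM (3.53 ± 0.46), and the transporter gene Slc16a9 from 0.290 ± 0.0201 to 3.31 ± 1.17 CPM (3.49 ± 0.41). Cxcl15 fell to 3.32 ± 0.171 CPM (-3.29 ± 0.13). Mal, a membrane proteolipid, fell from 9.33 ± 0.183 to 1.03 ± 0.243 CPM (-3.17 ± 0.22), and Abcd2, a peroxisomal fatty acid transporter, from 11.7 ± 1.93 to 1.43 ± 0.215 CPM (-3.03 ± 0.24). Sorcs1 (5.11), Acod1 (3.92) and Spib (3.60) rose and Tenm4 (-3.82) and Notum (-2.96) fell on the log2 scale. Extl1 reached 3.17 CPM, and Ror2 was at 0.125 CPM against 1.09 in control; both passed, with too few counts for a fold. Among family members and antisense genes, uncertain as above, Sprr2e (28.1 CPM), H2-M2 (3.50) and the olfactory receptor gene Olfr295 (1.23 from 0.0686) rose. H2-Q1 (4.23), Krtap1-5 (0.0716), Krt33b (0.0889) and Bcas3os2 (0.125) fell.

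Of 26 NF-κB targets, 13 rose with the combined exposure over all genes and 22 adjusted over the list alone, with none lower. Their median was 0.91 (camera adjusted p = 2.75e-23; adjusted p = 0.0871 with an estimated correlation). Tnfaip3, which encodes the inhibitor A20, rose from 70.1 ± 1.54 to 237 ± 2.91 CPM (1.76 ± 0.12). Tnfaip2 rose by 2.49 and Ccl2 to 924 ± 38.4 CPM (2.36 ± 0.17). Of 21 cytokines and chemokines 9 rose and Cxcl15 fell, or 16 and 1 adjusted over the list alone. They had a median of 0.83 (adjusted p = 2.16e-10; adjusted p = 0.262 with an estimated correlation). Cxcl16 (1.5), Ccl9 (1.96) and Ccl20 (1.4) were among those that rose. Of 28 interferon-stimulated genes 3 rose, or 7 adjusted over the list alone (median 0.24, adjusted p = 6.13e-05; adjusted p = 0.0878 with an estimated correlation). The 3 were the paralogs Gbp3 (1.23) and Gbp2 (1.21) and the antiviral GTPase Mx2 (0.52), while Oasl2 had 0.49. Of 14 MHC class I genes 0 passed over all genes in edgeR and 1 rose adjusted over the list alone. As a list they were higher (median 0.34, adjusted p = 0.00215; adjusted p = 0.504 with an estimated correlation). Tap2 stood at 0.86, Tapbp at 0.61, Psmb9 at 0.65 and Tap1 at 0.30 on the log2 scale. The death receptor gene Fas rose (20.6 ± 0.169 to 43.5 ± 2.75 CPM, 1.08 ± 0.16) and was the 1 gene called among 20 p53 targets, of which 1 rose and 2 fell adjusted over the list alone. The p53 list as a whole was lower (median -0.23, adjusted p = 0.0485; adjusted p = 0.262 with an estimated correlation). Perp had -0.56, Sesn2 -0.40 and Btg2 -0.32.

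Alb fell to 358 ± 15.5 CPM (-1.74 ± 0.14) and Afp to 608 ± 17.8 CPM (-1.35 ± 0.16) with the combined exposure. They were 2 of the 15 hepatocyte identity genes, of which 5 fell adjusted over the list alone (median -0.58, adjusted p = 6.30e-05; adjusted p = 0.0878 with an estimated correlation). Hnf4a (-0.58) and Foxa2 (-0.59) did not pass. Of 18 immediate early genes 3 fell, or 8 adjusted over the list alone (median -0.31, adjusted p = 0.000446; adjusted p = 0.262 with an estimated correlation). They were the transcription factor Klf4 (55 ± 5.21 to 24.3 ± 2.10 CPM, -1.18 ± 0.12), the phosphatase Dusp1 (-0.84) and the nuclear receptor Nr4a1 (-0.91), with Dusp6 at -0.45. Of 24 cholesterol genes Sqle fell (-0.65 ± 0.10), and 5 fell adjusted over the list alone (median -0.36, adjusted p = 1.04e-05; adjusted p = 0.0878 with an estimated correlation). Dhcr7 had -0.48, Nsdhl -0.44 and Hmgcs1 -0.39. Of 21 targets of NRF2, a regulator of antioxidant defence, the epoxide hydrolase Ephx1 (-0.73) and the glutathione synthesis gene Gclm (-0.45) fell. That is 2 over all genes and 2 adjusted over the list alone (median -0.39, adjusted p = 0.000122; adjusted p = 0.493 with an estimated correlation). Gstm1 had -0.55 and Nqo1 -0.57. Of 8 cholangiocyte markers Krt7 (-1.47) and Epcam (-1.34) fell, and 3 fell and 1 rose adjusted over the list alone (median -0.36, adjusted p = 0.0451; adjusted p = 0.262 with an estimated correlation). Spp1 had -0.59. Chaperones and degradation factors of the endoplasmic reticulum were lower as a list (21 genes, median -0.16, adjusted p = 0.0110; adjusted p = 0.262 with an estimated correlation). So were nuclear oxidative phosphorylation genes (25 genes, median -0.16, adjusted p = 0.0451; adjusted p = 0.841 with an estimated correlation). In both, 0 genes were called over all genes and 0 adjusted over the list alone in edgeR. Dnajc3 had -0.33, Xbp1 -0.39, Syvn1 -0.20 and Herpud1 -0.32. Cox5a had -0.37, Ndufa4 -0.33, Uqcrc2 -0.12 and Atp5c1 -0.24. Of 13 flavin monooxygenase and choline genes 0 passed in edgeR, also adjusted over the list alone (median -0.04, adjusted p = 0.233). Fmo2 had -0.67, Slc44a1 -0.37, Sardh -0.53, and Fmo1 stood at 0.143 CPM. Leaving out 1 library ended the list calls of p53 targets (any control, TMAO or combined library, adjusted p 0.0753 to 0.117) and of reticulum chaperones (combined 16, 0.0568). It ended that of oxidative phosphorylation (the same libraries as for p53 except control 16, 0.0522 to 0.328), whose mean of -0.18 was -0.085 without control 14. Cholangiocyte markers lost the call without any library but combined 14 (0.0516 to 0.186), and their mean of -0.60 was -0.38 without combined 16.

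The combined exposure changed 545 genes against control (314 higher, 231 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 357 of them at least 2-fold. Named genes passed at an adjusted p of 0.000165 (Pglyrp2) to 0.0449 (Gclm). The count was 2965 and 2956 without TNF-α 14 or 16, 89 and 94 without control 14 or 16, and 281 without TMAO 14 and also without TMAO 16. It was 90 and 101 without combined 14 or 16, 2373 when only the groups compared were fitted, and 3700 without TNF-α 16 and control 14, among them all 545. Of the 41 named genes that passed, all passed without either TNF-α library, 32 without either TMAO library, 18 without either control library, and 20 and 24 without combined 14 or 16. Those that lost the call without 2 or more libraries were Extl1, Olfr295, H2-M2, Gdnf, Slc16a9, Krtap1-5, Bcas3os2, Krt33b, Ror2, Cxcl16, Ccl20, Gbp2, Mx2, Fas, Ephx1, Gclm, Sqle, Afp, Klf4, Dusp1, Nr4a1, Krt7 and Epcam (adjusted p up to 0.391). Tenm4 (0.0537) and Ccl9 (0.0602) lost it without control 16 and Acod1 (0.0506) without control 14.

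TMAO alone was compared with control to find the genes that changed with the metabolite. The 24 measured genes of glycolysis and the hypoxia response were lower with TMAO as a list (median log2 fold change -0.23, camera adjusted p = 1.66e-17; adjusted p = 0.20 with an estimated correlation). Over all genes 0 of them were called, and 6 were lower adjusted over the list alone. Bnip3 (ENSMUSG00000078566.8), a mitophagy receptor induced by hypoxia, stood at 17.2 ± 0.483 CPM in control and 6.67 ± 0.124 with TMAO (n = 2 each; log2 fold change -1.37 ± 0.12, adjusted p = 0.146). The oxygen-sensing prolyl hydroxylase Egln3 stood at 33.0 ± 0.502 and 18.3 ± 1.35 CPM (-0.85 ± 0.11). Ndrg1, a gene induced by low oxygen, stood at 60.5 ± 1.49 and 37.9 ± 0.378 (-0.67 ± 0.09) and the phosphofructokinase Pfkp at 49.9 ± 0.532 and 37.8 ± 0.732 (-0.40 ± 0.10). Outside the list, Kctd11 stood at 16.4 ± 1.17 and 9.48 ± 0.568 CPM (-0.79 ± 0.11) and Smtnl2 at 2.48 ± 0.107 and 1.06 ± 0.0415 (-1.22 ± 0.25). Counted after the values were seen, 21 of the 24 list genes (87.5%) had both TMAO libraries below both control libraries and 0 the reverse. For comparison, 15.9% of all tested genes lay wholly lower and chance gives 16.7% for a single gene. The 24 genes were measured in the same libraries and can move together. They are not independent replicates, so the share of 87.5% does not measure how far chance is excluded. The list mean of -0.34 ran from -0.36 to -0.32 when 1 control or TMAO library was left out.

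No gene passed over all genes with TMAO alone by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 184 genes, where 781 are expected by chance. With only the TMAO and control libraries fitted it was reached by 552, so the spread shared with the TNF-α libraries lowered that number. Such a shortfall, here and in the contrasts below, is not evidence that nothing changed. By limma-voom 0 passed, and by DESeq2 4, all lower: Bnip3, Egln3, Ndrg1 and Kctd11. These were also the 4 that passed when only the TMAO and control libraries were fitted. Without TNF-α 14 there were 8: Bnip3, Egln3, Ndrg1, Kctd11, Fam162a, P4ha2, Ddit4 and Igfbp1. Without TNF-α 16 there were 9, these and Appl2, all lower. Without TNF-α 16 and control 14, 48 genes passed (4 higher, 44 lower), 13 of them among the 24 hypoxia genes and lower there. Fam162a, P4ha2, Ddit4, Igfbp1 and Appl2 were named after their values were seen. Genes with at least 10 CPM had a median 95% half-width of 0.41 on the log2 scale, or 1.33-fold, without adjustment over genes. Smaller changes of single genes were mostly not detectable at this spread, and larger ones could fail as well, as that of Bnip3 did. Simulated counts with known changes were also used for this comparison, over 15613 genes. There edgeR recovered 4.48% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 97.0% of those changed 4-fold. The simulated libraries included no outlying one, so these rates may differ from those of the real libraries.

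Of 5 measured markers of macrophages and Kupffer cells, 0 passed over all genes or adjusted over the list alone in edgeR with TMAO, and the list was lower (median -0.12, adjusted p = 0.0333; adjusted p = 0.839 with an estimated correlation). Aif1 had -0.78, Fcer1g -0.58, Csf1r -0.12 and Cd68 -0.10, and Aif1 stood at 0.767 and 0.446 CPM. That call ended without control 14, either TMAO library or either combined library (adjusted p 0.0531 to 0.713). Of 13 flavin monooxygenase and choline genes 0 passed in edgeR over all genes and 0 adjusted over the list alone (median 0.04, adjusted p = 0.682). Sardh stood at 0.953 CPM in control and 1.35 with TMAO (0.50), and choline kinase Chka at 196 and 215 (0.14). Fmo1 stood at 0.546 and 0.424 (-0.36) and Chkb at 0.836 and 0.670 (-0.32). Chkb lay at 0.37 with log2(TPM + 1) and at 0.07 without TMAO 16.

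**Figure D3:**
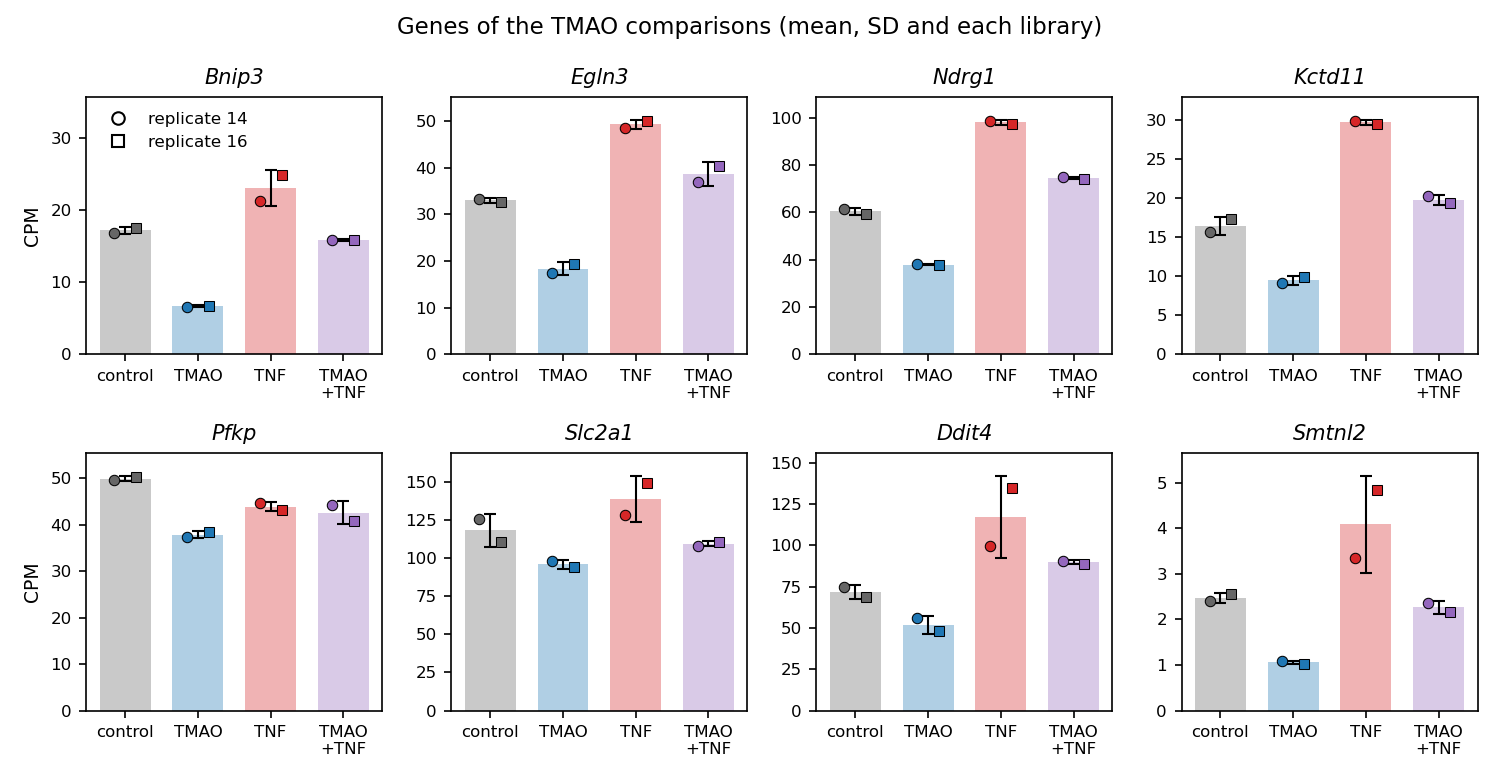
Expression of Bnip3, Egln3, Ndrg1, Kctd11, Pfkp, Slc2a1, Ddit4 and Smtnl2 in the 4 groups, in CPM (vertical axis); bars are means of 2 libraries, error bars the SD, and points the single libraries. Bnip3 stood at 17.2 ± 0.483 CPM in control, 6.67 ± 0.124 with TMAO, 23.1 ± 2.48 with TNF-α and 15.9 ± 0.0799 with both.

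The combined exposure was compared with TNF-α alone to find the genes that changed when TMAO was added to the cytokine. The 24 hypoxia and glycolysis genes were lower as a list (median -0.29, mean -0.17, camera adjusted p = 0.000546; adjusted p = 0.725 with an estimated correlation). In edgeR 0 were called over all genes and 2 were lower adjusted over the list alone. Bnip3 stood at 23.1 ± 2.48 CPM with TNF-α and 15.9 ± 0.0799 with both (n = 2 each; -0.54 ± 0.12, adjusted p = 0.569). Ndrg1 stood at 98.0 ± 0.976 and 74.5 ± 0.414 (-0.40 ± 0.09), Egln3 at 49.3 ± 0.957 and 38.6 ± 2.54 (-0.35 ± 0.11) and the glucose transporter Slc2a1 at 139 ± 15 and 109 ± 1.61 (-0.34 ± 0.12). Kctd11 stood at 29.7 ± 0.306 and 19.7 ± 0.638 CPM (-0.59 ± 0.11), Naa80 at 5.88 and 3.37, Fam229b at 0.852 and 0.179 and Cmya5 at 0.190 and 1.14. Counted after the values were seen, 17 of the 24 list genes (70.8%) had both combined libraries below both TNF-α libraries and 2 above, against 17.3% of all genes wholly lower. Here too the list genes are not independent replicates. Without TNF-α 16 the list mean was -0.08 and its adjusted p 2.56e-05.

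Another 7 lists were lower with the combined exposure than with TNF-α alone, each with 0 genes called in edgeR over all genes, 0 adjusted over the list alone, and an adjusted p = 0.725 with an estimated correlation. Ribosomal protein genes had a median of -0.47 (adjusted p = 3.36e-06; Rps19 -0.62, Rpl13 -0.60, Rpl27 -0.55, Rpl5 -0.46). Nuclear oxidative phosphorylation genes had -0.39 (adjusted p = 0.000242; Ndufs3 -0.54, Ndufa2 -0.62, Ndufv1 -0.45, Ndufa4 -0.54). Antioxidant enzymes had -0.37 (adjusted p = 0.00177; Prdx5 -0.58, Prdx6 -0.37, Msrb1 -0.51, Gpx4 -0.51). NRF2 targets had -0.19 (adjusted p = 0.0180; Hmox1 -0.30, Gsta4 -0.52, Gsta2 -1.25, Ephx1 -0.30). Cytokines and chemokines had -0.29 (adjusted p = 0.00124; Ccl5 -0.57, Cxcl2 -0.42, Ccl20 -0.38, Ccl7 -0.80). Immediate early genes had -0.17 (adjusted p = 0.0289; Klf2 -1.19, Dusp1 -0.26, Btg2 -0.21, Dusp5 -0.34), and the PERK-ATF4 stress response had -0.16 (adjusted p = 0.0448; Cebpb -0.62, Ddit4 -0.38, Ddit3 -0.55, Atf3 -0.33). None of these 7 passed without TNF-α 16. The adjusted p was then 0.886 for ribosomal proteins and for oxidative phosphorylation, whose means turned positive (0.0098 and 0.0115). It was 0.899 for antioxidant enzymes, 0.886 for NRF2 targets, 0.164 for cytokines, 0.0666 for immediate early genes and 0.874 for PERK-ATF4, with means of -0.037, -0.053, -0.084, -0.096 and -0.032 in that order. Without TNF-α 14 their means were -0.81 (ribosomal), -0.62 (oxidative phosphorylation), -0.55 (antioxidant), -0.34 (NRF2), -0.42 (cytokines), -0.28 (immediate early) and -0.22 (PERK-ATF4), against -0.41, -0.31, -0.30, -0.21, -0.26, -0.20 and -0.13 with all libraries. Immediate early genes also lost the call without TNF-α 14 or combined 16 (adjusted p up to 0.143), and PERK-ATF4 without any library but TNF-α 14 (0.0513 or more). Of the 13 flavin monooxygenase and choline genes 0 passed in edgeR, also adjusted over the list alone (median 0.09, adjusted p = 0.682), with Pemt at -0.40, Chka at 0.25, Pcyt1a at 0.27 and Aldh7a1 at -0.15. Without TNF-α 16 Pcyt1a lay at -0.040 and Aldh7a1 at 0.034.

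No gene differed over all genes between the combined exposure and TNF-α alone by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (549 at an unadjusted p under 0.05, 781 expected by chance; limma-voom 0, DESeq2 0). Without TNF-α 14, which leaves TNF-α 16 alone in its group, 8043 genes passed. Without TNF-α 16 and control 14 there were 13 (4 higher, 9 lower). Those lower included Ndrg1, Egln3, Slc2a1 and Kctd11, named after their values were seen.

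The interaction of TMAO and TNF-α asked whether the change with TMAO differed with and without the cytokine. Bnip3 had an interaction of 0.82 ± 0.17 on the log2 scale (n = 2 per group, adjusted p = 0.953), its change with TMAO being -1.37 without TNF-α and -0.54 with it. No gene passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (184 at an unadjusted p under 0.05, 781 expected by chance; limma-voom 0, DESeq2 0), with a median half-width of 0.58, or 1.5-fold. The other genes with the smallest p had low levels, given in the order control, TMAO, TNF-α and both. Nod2, a sensor of bacterial muramyl peptides, stood at 0, 0.102, 0.811 and 0.375 CPM, and Apol7d at 0.170, 0.544, 0.827 and 0.482. Olfr544 stood at 0.359, 0.0857, 0.182 and 0.499, and Cmya5 at 0.802, 0.669, 0.190 and 1.14. Ribosomal protein genes passed as a list (median -0.38, adjusted p = 0.000677; adjusted p = 0.917 with an estimated correlation; Rpl27 -0.49, Rpl13 -0.52, Rps19 -0.51, Rps2 -0.43). So did nuclear oxidative phosphorylation genes (median -0.30, adjusted p = 0.0125; adjusted p = 0.917 with an estimated correlation; Ndufa2 -0.63, Cox5b -0.51, Ndufb5 -0.43, Ndufv1 -0.35). Both had 0 genes called in edgeR over all genes and 0 adjusted over the list alone. Their means of -0.32 and -0.24 turned to 0.10 and 0.093 without TNF-α 16 (adjusted p = 0.0115 and 0.0626) and were -0.72 and -0.54 without TNF-α 14. Without control 16 they were -0.21 and -0.14 (adjusted p = 0.0616 and 0.299), and oxidative phosphorylation had an adjusted p of 0.0671 without combined 16. The hypoxia list did not pass (camera adjusted p = 0.0626, 1 gene higher adjusted over the list alone). Without TNF-α 16 its mean was 0.27, from a fit with TNF-α 14 alone in its group that was not repeated with an estimated correlation. Without TNF-α 14, 5800 genes passed, and without TNF-α 16 and control 14 Bnip3 passed alone (0.97, adjusted p = 0.00310). Of the 13 flavin monooxygenase and choline genes Pemt had -0.45, Fmo1 0.99, Chkb 0.63 and Sardh -0.40, and 0 passed in edgeR, also adjusted over the list alone. Chkb lay at -0.80 with log2(TPM + 1).

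TNF-α was also compared in the presence of TMAO, where the combined exposure against TMAO alone shares no library with TNF-α against control. There 569 genes passed (337 higher, 232 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among them were 16 of 26 NF-κB targets, all higher, or 22 adjusted over the list alone (median 0.99, adjusted p = 8.30e-26; adjusted p = 0.0718 with an estimated correlation). Ccl2 stood at 166 ± 2.10 CPM with TMAO and 924 ± 38.4 with both, Vcam1 at 55.3 ± 0.532 and 254 ± 3.97, and Alb at 1104 ± 17.9 and 358 ± 15.5, and all 3 passed. Of the 24 hypoxia genes 3 rose (3 adjusted over the list alone; median 0.18, adjusted p = 0.000243; adjusted p = 0.315 with an estimated correlation). The count was 302 and 303 without control 14 or 16, 72 and 77 without TMAO 14 or 16, and 2608 and 2606 without TNF-α 14 or 16. It was 105 and 106 without combined 14 or 16, 4844 when only the groups compared were fitted and 4830 without TNF-α 16 and control 14. Across genes, which are not independent replicates, the log2 fold changes of these separate comparisons had a Pearson correlation of 0.69. Of the 633 genes called with TNF-α alone, 632 had the same sign in the presence of TMAO. Both comparisons called 268 genes higher (8.03 by chance) and 198 lower (3.88 by chance), and 0 in opposite directions. The chance values assume calls independent between the comparisons. Both comparisons use the same estimate of each gene's spread from 1 fit, so these values may be too low. Without TNF-α 14, 4759 of 7966 called genes (59.7%) kept their sign, and 224 genes were called in opposite directions. Without any 1 of the other libraries 0 were opposite, and the shared calls ran from 38 higher and 34 lower (TMAO 14) to 967 and 758 (TNF-α 16). The matching pair for TMAO (TMAO against control, and the combined exposure against TNF-α) had a Pearson correlation of 0.22 across genes. That correlation fell to 0.0136 without control 14 and to 0.0177 without TNF-α 16, the 2 libraries that departed the same way.

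**Figure D4:**
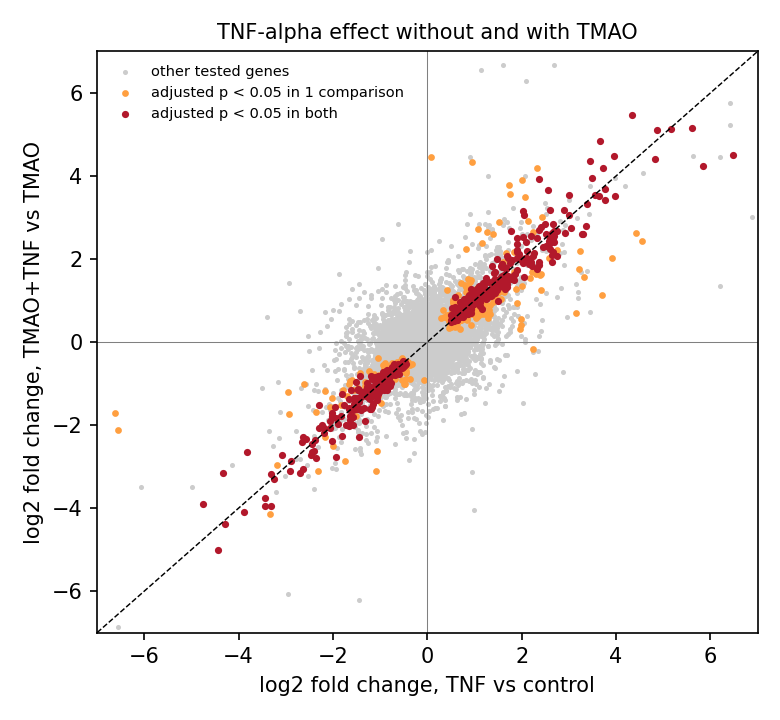
Log2 fold change with TNF-α against control (horizontal axis) and with TMAO and TNF-α against TMAO alone (vertical axis) for each of 15613 genes; red genes passed in both comparisons, orange genes in 1 of them, grey in neither, the dashed line marks equal values, and 5 genes lie outside the axes. Of the red points 268 lie in the upper right and 198 in the lower left.

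Averaged over TMAO, TNF-α changed 1437 genes (835 higher, 602 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 628 at least 2-fold. Without 1 library the count was 729 and 705 (control 14 and 16), 673 and 655 (TMAO 14 and 16), 7414 and 3947 (TNF-α 14 and 16) and 698 and 684 (combined 14 and 16), and it was 5494 without TNF-α 16 and control 14. Averaged over TNF-α, TMAO changed 0 genes in edgeR (453 at an unadjusted p under 0.05, 781 expected by chance; limma-voom 0, DESeq2 4, again Bnip3, Egln3, Ndrg1 and Kctd11). Fits without TNF-α 14 or without TNF-α 16 left 1 library in the TNF-α group, in the first case the outlying TNF-α 16. Gene counts from these fits therefore cannot be read as changes with TMAO. The hypoxia list was lower with TMAO in this average (median -0.25, adjusted p = 7.32e-10; adjusted p = 0.543 with an estimated correlation; 0 called over all genes, 5 lower adjusted over the list alone).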

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

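Of the tests in this part, those of gene length and GC content, of a wrong label and of unspliced or nuclear RNA were chosen only after the result was seen, as was leaving out TNF-α 16 together with control 14. Ribosomal protein genes (28 measured) and nuclear genes of oxidative phosphorylation (25 measured) stood out because their change with TMAO differed with and without TNF-α in a test of the difference. The mean of the fitted interactions over the list was -0.38 for ribosomal proteins and -0.28 for oxidative phosphorylation, and the mean of log2 CPM differences was -0.32 and -0.24 (camera adjusted p = 0.000677 and 0.0125; adjusted p = 0.917 with an estimated correlation for both). Both lists were highest in TNF-α 16 (10.50 and 7.18 mean log2 CPM, against 9.66 and 6.52 in TNF-α 14), and without that library the mean of log2 CPM differences was 0.10 and 0.093 (adjusted p = 0.0115 and 0.0626). With TNF-α 16 and control 14 both left out it was 0.0045 and 0.0087.

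TNF-α 16 differed from TNF-α 14 with an SD of 0.77 on the log2 scale over genes, and the tables argue against gene length and GC content as the whole cause, since the SD was still 0.707 after both were corrected for. They also argue against a library from a group without TNF-α, since its NF-κB target mean lay 1.15 above the highest library without TNF-α; this says nothing on a label within the TNF-α groups. Fewer reads from unspliced or nuclear RNA in TNF-α 16 remains a candidate explanation: 496 genes of the annotation class TEC, mostly unspliced transcripts, had a median log2 difference of -1.06 between TNF-α 16 and 14 against -0.04 for protein-coding genes of matched level, a gap of -1.02 that lay below all 10000 random matched sets. In the other groups the gap was taken against all protein-coding genes, not matched on level. It was 0.40 between control 16 and 14, -0.02 in the TMAO group and -0.02 in the combined group. The nuclear 7SK RNA gene Rn7sk went the other way, at 92.5 CPM in TNF-α 16 and 2.71 in TNF-α 14, so the gap of the TEC genes does not extend to every nuclear RNA. Rn7sk also stood at 95.3 CPM in combined 14 and 0.567 in combined 16, where the TEC gap was -0.02, so it did not follow that gap. No biological explanation was tested, since both libraries carry the same treatment labels.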

How the results depend on the processing

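Leaving out TNF-α 16 together with control 14, the library weights and the offset for gene length and GC content were chosen after the data were seen; the other settings were planned. Of the 79 calls on named genes, 79 were kept by DESeq2 and with RLE scaling, 78 by limma-voom, with total count scaling and with the length and GC offset, 76 with no filter, 64 and 63 on log2(TPM + 1) and log2(TPM + 0.1), 67 with library weights, 44 with only the groups compared, 39 to 79 without 1 library and 79 without TNF-α 16 and control 14; none turned direction. Of 41 list calls, RLE and total count scaling kept 41, log2(TPM + 1) 36, fry 22 and an estimated correlation 0. The biological coefficient of variation was 16%, 5.53% without TNF-α 16 and 2.79% without both libraries. The cause of the changes below was not tested, except where a smaller set of libraries or a fold limit sets it by construction.

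Counts of called genes follow in the order TNF-α against control (633), both against control (545), both against TMAO (569) and TNF-α averaged (1437). DESeq2 gave 960, 899, 908 and 1749, no filter 954, 895, 898 and 1792, the length and GC offset 932, 880, 896 and 1952, log2(TPM + 1) 314, 332, 332 and 922, log2(TPM + 0.1) 270, 296, 306 and 890, library weights 199, 2389, 3875 and 1234, a limit of 2-fold 395, 357, 356 and 628, and leaving out TNF-α 16 and control 14 gave 3278, 3700, 4830 and 5494. With only the groups compared the first 3 counts were 3, 2373 and 4844. Leave-one-out counts ran from 92 to 7966, 89 to 2965, 72 to 2608 and 655 to 7414. The highest came without TNF-α 14, and both against control and both against TMAO had nearly as many without TNF-α 16 (2956 and 2606). For TMAO against control (0) DESeq2 gave 4, no filter 2, only the groups compared 4, library weights 4, leaving out both libraries 48, and leave-one-out fits 0 to 9. For TMAO averaged (0) DESeq2 gave 4, no filter 7, library weights 1, leaving out both libraries 65 and leave-one-out fits 0 to 7327. Both against TNF-α (0) gave 13 without both libraries and 0 to 8043 without 1, and the interaction (0) gave 1 and 0 to 5800.

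The number of a library (14 or 16) was not shown to pair the samples: correlations of the deviations of same-numbered libraries were -0.42 between control and TNF-α and -0.0461 to 4.34e-05 between the other pairs of groups. With the number as a block the counts were 342, 301, 323 and 1011 in the order above and 0 for the 4 contrasts that had 0; 62 of 79 named calls and 39 of 41 list calls were kept.

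The hypoxia list with TMAO had a mean of -0.34 and passed neither with an estimated correlation (adjusted p = 0.20) nor by fry (-0.34, 0.109), and ranged from -0.36 to -0.32 without 1 library. With both against TNF-α it had -0.17 (estimated correlation 0.725, fry 0.308) and -0.24 to -0.08. NF-κB targets lost the call with an estimated correlation at 1.11 with TNF-α and at 1.01 with both (adjusted p = 0.0891 and 0.0871), with 1.07 to 1.16 and 1.01 to 1.04 without 1 library. The correlation of separate comparisons was 0.69 for TNF-α, 0.48 by Spearman, 0.81 with at least 1 CPM in 2 libraries and 0.39 to 0.68 without 1 library; for TMAO it was 0.22, 0.38, 0.39 and 0.0136 to 0.31, and turned to -8.23e-05 without both libraries.

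Over all settings, values of lists and named genes turned direction 42 times. Those that turned without TNF-α 16 are given from that fit to the fit without TNF-α 14, the opposite end of their range without 1 library. With TNF-α against control, ribosomal proteins ran from -0.15 to 0.67 (-0.053 without both libraries), Rps19 from -0.11 to 0.84, Rpl5 from -0.068 to 0.66, Rpl13 from -0.13 to 0.79 and Rpl19 from -0.13 to 0.74. With both against TNF-α, ribosomal proteins ran from 0.0098 to -0.81 and oxidative phosphorylation from 0.0115 to -0.62 (0.0098 and 0.0115 without both libraries). Gpx4 ran from 0.026 to -0.88 and Aldh7a1 from 0.034 to -0.29, with 0.026 and 0.034 without both libraries. Pcyt1a ran from -0.040 without TNF-α 16 to 0.69 without TNF-α 14 and was -0.040 without both. Aldh7a1 also lay at 0.31 in both TPM fits, Btg2 at 0.0023 and 0.0025, Chka at -0.0052 with the length and GC offset, and PERK-ATF4 at 0.059 with log2(TPM + 1). In the interaction, ribosomal proteins ran from 0.10 to -0.72 and oxidative phosphorylation from 0.093 to -0.54, and were 0.0045 and 0.0087 without both libraries. Rpl27 ran from 0.030 to -0.85, Rpl13 from 0.033 to -0.89, Rps19 from 0.069 to -0.89 and Rps2 from 0.048 to -0.76. Cox5b ran from 0.067 to -0.90, Ndufb5 from 0.043 to -0.76 and Ndufv1 from 0.028 to -0.63. Chkb lay at -0.80 and -0.83 in the TPM fits. With TMAO against control, Chkb lay at 0.37 and 0.39 with log2(TPM + 1) and log2(TPM + 0.1), at 0.066 without TMAO 16 and at -0.84 without TMAO 14. Csf1r lay at 0.016 and 0.021 and Cd68 at 0.028 and 0.029 in the TPM fits. The median gene of the interaction lay at -0.0092 with TMM and 0.026 with total count scaling, the widest move of any contrast. No scaling moved the share of higher calls by over 10 percentage points.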

Other observations

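The genes named in the next paragraph and in the last, the tests of an outlying control library and of leukocyte transcripts, and the library weights were chosen only after the values were seen; the test of scaling and the splits of the samples were written before.

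Averaged over TMAO, TNF-α moved genes of the complement, acute phase, matrix and coagulation lists in both directions, and these lists did not pass camera. Single genes were tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (log2 fold change ± SE, n = 4 libraries per side). Of 14 complement genes 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.236; fry for change in either direction, adjusted p = 7.09e-06). The central component C3 (ENSMUSG00000024164.15) rose from 438 ± 16 to 936 ± 201 CPM with TNF-α and 1048 ± 10.2 with both (1.22 ± 0.12), and C5 (Hc) rose (1.17 ± 0.12). Cfi, a protease that degrades active C3, fell (-1.29 ± 0.09). Of 7 acute phase genes 3 rose and 2 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.996; median -0.27 and mean 0.19). Those named here are the interleukin-1 antagonist Il1rn (1.53 ± 0.07) and ceruloplasmin Cp (0.65 ± 0.08), which rose, and fibrinogen beta Fgb, which fell (79.7 ± 2.79 to 26.7 ± 2.98 CPM with TNF-α, -1.69 ± 0.08). Of 20 matrix and TGF-beta target genes 4 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.546). The matrix proteases Mmp9 (1.57 ± 0.09) and Mmp13 (1.53 ± 0.07) rose, and the YAP and TGF-beta target Ccn2 (114 ± 9.18 to 21.9 ± 2.82 CPM with TNF-α, -2.38 ± 0.09), Tgfbi (-2.54 ± 0.12) and Thbs1 (-1.24 ± 0.22) fell. Of 12 coagulation genes 2 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.848; median 0.18 and mean -0.34, with camera's direction up). Protein C (Proc) fell (-1.79 ± 0.13). Of the 24 hypoxia genes Ndrg1 (0.84 ± 0.06), Egln3 (0.83 ± 0.08) and Bnip3 (0.84 ± 0.08) rose (3 adjusted over the list alone; list median 0.17, adjusted p = 0.00171; adjusted p = 0.352 with an estimated correlation). Of the 13 flavin monooxygenase and choline genes 3 fell (4 adjusted over the list alone; adjusted p = 0.130), among them Fmo2 (-0.69 ± 0.13) and the choline transporter Slc44a1 (-0.42 ± 0.08). Of these 17 genes, 14 or more passed in every leave-one-out fit. Thbs1 and Slc44a1 lost the call without any control, TMAO or combined library (adjusted p up to 0.0853 and 0.141) and Fmo2 without any of these but combined 16 (up to 0.101). In both TPM fits Cp (adjusted p = 0.0630 and 0.0618), Fmo2 (0.0702 and 0.0792) and Slc44a1 (0.231 and 0.235) lost it, as did Fmo2 with library weights (0.123) and Slc44a1 with the library number as a block (0.0542).

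Every split of the 8 libraries into equal groups other than the one that separates the remaining agent was fitted with that agent kept in the model, which gives 34 splits for each agent. For TNF-α 1 of 34 splits, the real one, gave as many genes (1715 in this model, with 0 as the highest of the others). The other splits mix libraries with and without TNF-α, which widens the spread they are tested against. They could therefore hardly give calls, and the comparison with them does not exclude chance. For TMAO the real split gave 0 genes, as did the highest of the others (0). All splits therefore had to give as many (34 of 34), and this says nothing on chance or on smaller effects.

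The lower hypoxia and glycolysis genes with TMAO are a hypothesis found and tested on the same 2 libraries per group. The tables argue against control 14 as their source in TMAO against control, since without it the mean log2 fold change of the 24 genes was -0.34. Leaving out TNF-α 16 cannot test that comparison, which has no TNF-α library. In both against TNF-α the list mean of -0.17 was -0.08 without TNF-α 16, so a share of that change rested on this library. A wrong scaling factor moves all genes of a library alike, and relative to the median gene the mean with TMAO was -0.34, which argues against scaling as the whole cause. The call of the list was lost with an estimated correlation (adjusted p = 0.20). A response to TMAO itself, or a difference in oxygen, cell density or medium between the dishes, may account for it, and neither was tested.

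Rn7sk, the 7SK RNA gene, stood at 92.5 CPM in TNF-α 16 and 95.3 in combined 14, and at 0.567 to 3.43 in the other 6 libraries. Celf2 (3.02 and 5.32 CPM) and Tmsb4x (3.43 and 5.39) were also higher in these libraries than elsewhere (at most 0.586 and 0.331), and Btk was at 4.71 CPM in TNF-α 16 and at 0 in the other 7. Of 13 abundant leukocyte transcripts, 0 reached both 10 counts in TNF-α 16 and 3 times the highest of the other 6 libraries. The most abundant, Cd74, stood at 13.9 CPM there, 6.82 in TNF-α 14, 8.30 and 8.19 in the combined libraries and 1.96 to 2.5 without TNF-α. Celf2 and Tmsb4x were themselves only at 3.02 and 3.43 CPM in TNF-α 16. A trace of leukocytes could leave most of the 13 under the limit, so the test cannot decide on such a trace. Combined 14 was not tested. No biological explanation was tested.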
